A study of Mus musculus with 12 samples.

How the data were processed

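RNA sequencing was done on total RNA of mouse peritoneal macrophages, the resident macrophages of the abdominal cavity, from 4 genotypes: wild type (WT), SAMHD1 knockout (SAMHD1 KO), MDA5 knockout (MDA5 KO) and the knockout of both genes (SAMHD1 MDA5 DKO). Each genotype had 3 libraries, all untreated at day 0. The labels do not say whether the 3 libraries of a genotype came from separate animals. SAMHD1 is an enzyme that breaks down deoxynucleotides, and MDA5, encoded by Ifih1, is a cytosolic sensor of long double-stranded RNA.

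The authors deposited 6 tables, each with 6 libraries of a pair of genotypes. Per the labels, the processing names STAR, Salmon, R 4.1.2 and DESeq2, with the builds GRCm38 and mm10. The extraction note also names pBWA 0.5.9-r32-MPI-patch2, bedtools 2.16.2 and Ensembl Gene 61, and no label says which of these made the tables. The library columns deposited by the authors hold log2 values. These were found, from the values, to be variance-stabilised reads scaled within each table, after which the mean difference between 2 sets of libraries had been subtracted gene by gene. The sets were WT 3, SAMHD1 KO 2 and SAMHD1 MDA5 DKO 3 on one side and the other 9 libraries on the other. No label gives a reason for this adjusted set. In the 3 tables with MDA5 KO, the lone adjusted library was thereby set to the mean of the other 5, so that it holds no information of its own there. The deposited fold changes and standard errors are on the log2 scale and are shrunken towards 0. In the genes checked, the deposited p is that of the shrunken fold change divided by its standard error. The authors' counts of genes called therefore carry the shrinkage as well. The mean column deposited by the authors is a signal, the mean of reads divided by size factors. The authors' deposited p-value columns hold a p-value and an adjusted p with a weight beside it, and the weight was not used here. Their adjusted p is not a plain Benjamini-Hochberg value, since it can lie below their p. For Samhd1 in SAMHD1 MDA5 DKO minus SAMHD1 KO it was 0.812 against a p of 0.865. Their counts also cover 27706 to 31499 genes per table, so that they are not on the same footing as those of limma below. Genes on X, Y and the mitochondrial chromosome number 0 in all 6 tables.

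Whole read numbers per gene and library were solved from the stabilised values, the size factors and the means of the 6 tables together. A value within 0.05 reads of a whole number counted as whole, and 99.9% to 100.0% of genes per table met this. The 3 tables that share a library disagreed in 0 genes for each of the 12 libraries. The method was tested on simulated data, where all genes solved as whole were correct. A total of 33641 genes was recovered. Of these, 33502 were matched by identifier in GENCODE release M21, and 30343 had the same coordinates there. The positions printed are those of the files, on GRCm38. Recovered totals ran from 33234361 reads (WT 3) to 58345425 (SAMHD1 MDA5 DKO 1). Recovered reads are not a deposited count column, so that count models were not used, and the alternatives planned with them were replaced by others as given in the closing section. Sequencing reads without molecular identifiers are not independent molecules, so read numbers cover counting error only.

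Reads were divided by median-of-ratios size factors over the 12 libraries, and log2(value + 1) was taken. Genes with a CPM of at least 0.228 (10 reads in the median library) in at least 3 libraries were kept, 15130 in all. The design, the tests, the 27 gene lists and the rule for named genes were fixed before the data were examined. limma 3.58.1 in R 4.3.3 fitted all 12 libraries at once with genotype as the only term, a variance trend and robust moderation, with Benjamini-Hochberg adjustment over all genes tested at 0.05. There were 6 pairwise comparisons and the interaction, (SAMHD1 MDA5 DKO minus SAMHD1 KO) minus (MDA5 KO minus WT). Standard errors are those of limma. Of the lists, 24 had at least 3 tested members and went into camera with the preset correlation of 0.01, again with an estimated correlation, and into fry, each adjusted over the lists of a comparison. Across 182 tests of a list in a comparison, the neighbour lists included, the median, the mean and the direction of the test differed in sign in 32, of which 0 passed. The mean log2 value over the type I interferon list was compared between genotypes with a two-sided exact permutation test, for which 3 libraries against 3 give 20 assignments and a smallest p of 0.1. On simulated reads with 3 libraries per genotype, the fit recovered 13% to 36% of genes changed by a factor of 2 and 65% to 81% of those changed by a factor of 4. It made 3 to 10 false calls per comparison and called 0 of 27 unchanged lists in each of 6 comparisons. The changed genes had a mean of at least 50 normalised reads, and no simulated library stood apart as WT 3 does. The shares recovered can therefore differ from those in the real libraries. The simulated genes were independent, which leaves camera's preset correlation untested. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for the recovery and the figures.

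Named genes are Samhd1 and Ifih1 everywhere, and the called genes with the largest change whose groups do not overlap (up to 10 in each direction in the comparisons of SAMHD1 KO with WT and with SAMHD1 MDA5 DKO, up to 5 elsewhere). From each list, up to 4 members with the smallest p are named. Predicted genes and pseudogenes are not named, and genes named outside this rule are said to be chosen after their values were seen.

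The alternatives fixed with the design were limma without trend, no filter, a mean of at least 50 reads, pairwise fits, the replicate number as a block, pseudocounts of 0.1 and 10, a log2 fold change of at least 1, an estimated correlation, the median of the interferon list or its members with at least 50 reads, and each library left out in turn. Where a genotype kept 2 libraries, the spread was still shared across genotypes. Added after seeing the data were trimmed mean of M-values and total-read scaling, the adjusted set as a term, voom weights, voom with library quality weights, voom with WT 3 left out, array quality weights, SAMHD1 KO 2 and 3 averaged, WT 3 left out of the shared spread, WT 3 and MDA5 KO 2 left out together, the deposited log2 values of each table alone, and the interferon list in the libraries outside the adjusted set. Camera was first run without a variance trend and adjusted over 27 lists, neighbour lists included, and that version is kept as an alternative too. Not every gene that the rule names is reported here.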

Results

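The data were 12 libraries of untreated mouse peritoneal macrophages at day 0, 3 each of WT, SAMHD1 KO, MDA5 KO and SAMHD1 MDA5 DKO. Recovered totals per library were 44120812, 39397542 and 33234361 reads in WT, 52808132, 38597157 and 35827769 in SAMHD1 KO, 47795569, 33605499 and 46545165 in MDA5 KO, and 58345425, 44217718 and 43702245 in SAMHD1 MDA5 DKO (libraries 1, 2 and 3). Values below are normalised reads or log2 differences with their standard error, with 3 libraries per genotype. The series title asks about activation of MDA5 where SAMHD1 is missing. Interferon-stimulated genes, the usual readout of such sensing, were therefore the first of the gene lists.

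Samhd1 (ENSMUSG00000027639, chromosome 2, 157097533 to 157135265) gave 17120, 15520 and 7067 normalised reads in the WT libraries and 17460, 14950 and 16060 in MDA5 KO. The SAMHD1 KO libraries held 3689, 3253 and 2954, and the SAMHD1 MDA5 DKO libraries 4960, 3331 and 1747, so all 6 libraries of the targeted genotypes lay below the 6 others. WT 3 had 43.3% of the mean of the other WT libraries. Ifih1 (ENSMUSG00000026896, chromosome 2, 62595798 to 62646255) gave 3357, 2421 and 816 normalised reads in WT and 3745, 3163 and 3172 in SAMHD1 KO. In MDA5 KO it gave 0.855, 19.98 and 0, from 1, 16 and 0 reads, and in SAMHD1 MDA5 DKO 4.18, 0.881 and 41.9, from 6, 1 and 43 reads. In the deposited tables of the authors, the Ifih1 difference of MDA5 KO minus WT, shrunken towards 0, was -0.26 with an adjusted p of 0.328. No label says whether that fit used the subtracted values.

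**Figure D1:**
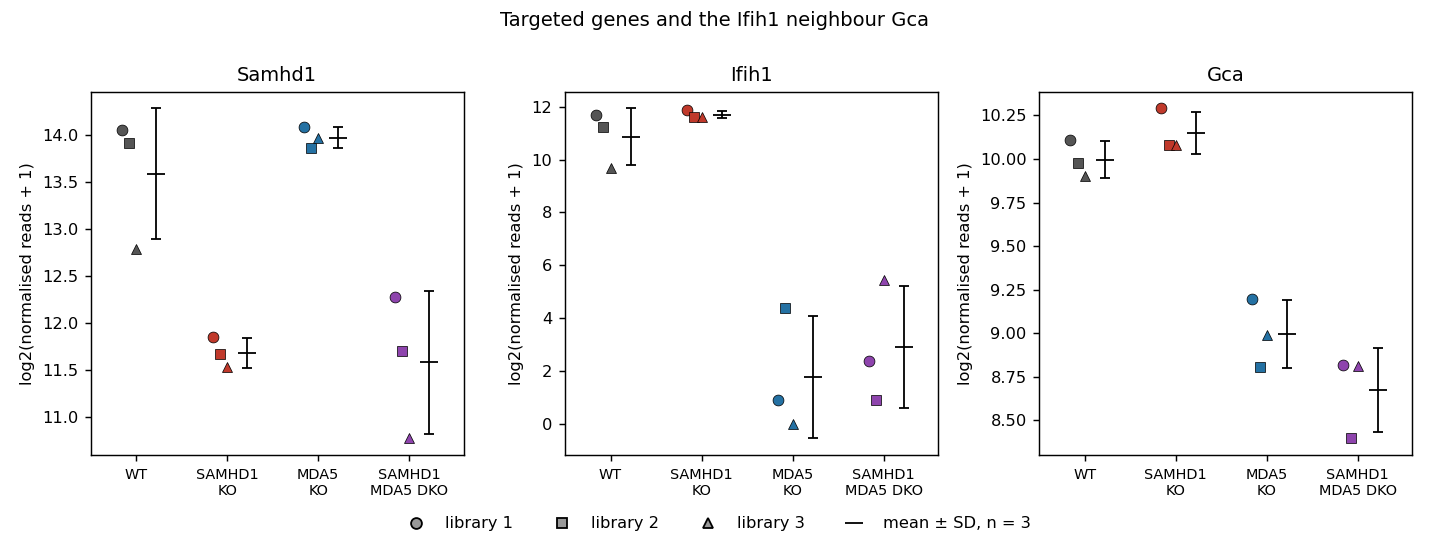
Log2 of normalised reads plus 1 for Samhd1, Ifih1 and its neighbour Gca in each of the 12 libraries, by genotype; black bars give the mean and SD of 3 libraries. Samhd1 was 7067 normalised reads in WT 3 against 17120 and 15520 in the other WT libraries, and Ifih1 was at most 41.9 in the MDA5-deficient libraries.

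SAMHD1 KO was compared with WT to ask which genes change when SAMHD1 is lost with MDA5 present. Interferon-stimulated genes were higher in SAMHD1 KO, with 81 of 94 tested members of the type I interferon list above WT and a median difference of 0.63. Ifi44, a gene induced by type I interferon, differed by 3.69 ± 0.83, and Slfn4 by 3.15 ± 0.83, or 1.94 without WT 3. Rsad2, which encodes the antiviral enzyme viperin, differed by 1.88 ± 0.50, and Helz2 by 1.31 ± 0.28. The list rose in camera (adjusted p = 2.15e-12, or adjusted p = 0.622 with an estimated correlation), and 10 members were up and 0 down when adjusted over the list alone. Targets of interferon gamma and IRF1 also rose as a list, with 20 of 22 members positive (adjusted p = 2.47e-05, or adjusted p = 0.622 with an estimated correlation) and 6 up adjusted over the list alone. Among them Gbp6 and Iigp1, both GTPases of host defence, differed by 2.01 ± 0.51 and 2.22 ± 0.61.

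Inflammatory NF-kB targets rose as a list in SAMHD1 KO, with 21 of 26 members positive (adjusted p = 4.9e-04, or adjusted p = 0.622 with an estimated correlation) and 5 up adjusted over the list alone. Nfkbiz differed by 1.72 ± 0.44 and Birc3 by 1.06 ± 0.29. Cell cycle genes fell as a list, with 38 of 40 members negative (adjusted p = 1.79e-07, or adjusted p = 0.622 with an estimated correlation), and Rrm1 and Mcm5 differed by -1.01 ± 0.34 and -1.92 ± 0.70, or -0.57 and -0.93 without WT 3. Genes of dNTP metabolism fell (20 of 24 negative, adjusted p = 0.00293, or adjusted p = 0.622 with an estimated correlation), Rrm1 being a member of both lists and Nme1 differing by -0.90 ± 0.32, or -0.46 without WT 3. Cholesterol biosynthesis fell too (17 of 20 negative, adjusted p = 1.4e-04, or adjusted p = 0.622 with an estimated correlation), with Msmo1 at -0.71 ± 0.22 and Mvd at -0.71 ± 0.26. No member of these 3 falling lists passed adjusted over the list alone. T cell markers fell as a list (8 of 9 negative, adjusted p = 0.0428, or adjusted p = 0.622 with an estimated correlation). Of these, Icos was up and Cd4 was among the 2 down adjusted over the list alone, at 2.11 ± 0.63 (1.38 without WT 3) and -3.37 ± 1.08. The T cell mean was 6.13 in WT 2 against 3.02 and 4.11 in the other WT libraries. The cell cycle mean was 5.90 in SAMHD1 KO 1 against 8.47 and 8.45 in the other SAMHD1 KO libraries, and 9.72 in WT 3. Camera's adjusted p was 0.676 without SAMHD1 KO 1 for the cell cycle, 0.0899 without WT 1 for cholesterol biosynthesis, and 0.309 without WT 3 and 0.117 without SAMHD1 KO 1 for dNTP metabolism. For T cells it was 0.783 without WT 2, 0.0624 without SAMHD1 KO 2 and 0.0847 without SAMHD1 KO 3.

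Over all 15130 genes, limma called 0 between SAMHD1 KO and WT, with a smallest adjusted p of 0.312 and 2336 genes at an unadjusted p under 0.05. Samhd1 itself, at -1.91 ± 0.37, had an adjusted p of 0.312. voom called 0, or 2771 with library quality weights, and limma with array quality weights called 6829. The authors' table has 115 up and 53 down, with 12 of the type I interferon list up and 0 down. Without WT 3 limma called 1 gene and without SAMHD1 KO 1 it called 2. Groups did not overlap in 20.2% of genes, where chance gives 10%.

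Averaged over the 94 genes, the interferon list stood at 10.78, 10.65 and 10.66 in the SAMHD1 KO libraries and at 10.25, 10.13 and 8.96 in WT. The difference of 0.91 had an exact permutation p of 0.1, the smallest that 3 libraries against 3 can give. Without WT 3 the difference was 0.50. It was 0.53 among the libraries outside the adjusted set and 1.69 between the lone pair inside it.

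**Figure D2:**
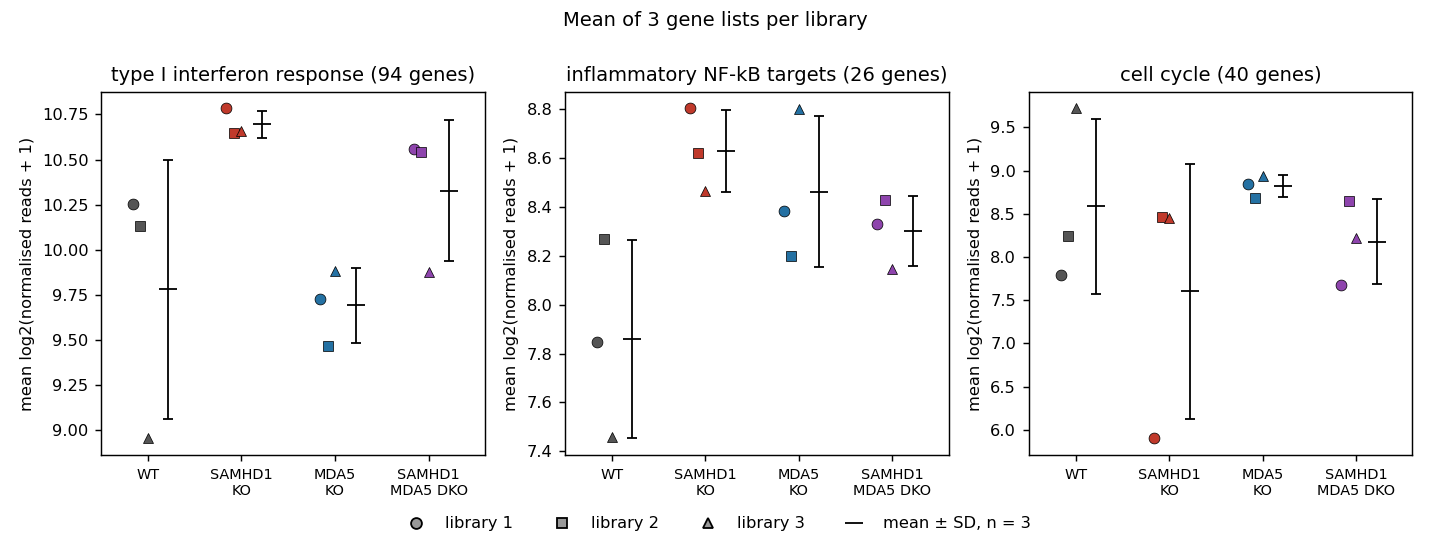
Mean log2 of normalised reads plus 1 over the type I interferon, inflammatory NF-kB and cell cycle lists in each of 12 libraries; black bars give the mean and SD of 3 libraries. The interferon mean was 8.96 in WT 3 and from 10.65 to 10.78 in SAMHD1 KO, and the cell cycle mean was 5.90 in SAMHD1 KO 1.

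SAMHD1 MDA5 DKO was compared with SAMHD1 KO to ask which of these genes move when MDA5 is lost in addition. Interferon-stimulated genes were lower on average in SAMHD1 MDA5 DKO, with 70 of 94 members negative and a median difference of -0.28. Ifi27l2a differed by -1.59 ± 0.45, Usp18, a negative regulator of interferon signalling, by -1.35 ± 0.44 (-0.82 without SAMHD1 MDA5 DKO 3), and Irf7, the transcription factor that amplifies the interferon response, by -0.86 ± 0.33. The list fell in camera (adjusted p = 2.6e-04, or adjusted p = 0.83 with an estimated correlation), with 0 members passing adjusted over the list alone. The difference in list means, -0.37, was -0.32 without SAMHD1 KO 1 (camera's adjusted p = 0.27) and -0.14 without SAMHD1 MDA5 DKO 3 (adjusted p = 0.148), and the call was also lost with voom's library quality weights (0.506) and array quality weights (0.442). Interferon gamma and IRF1 targets fell (18 of 22 negative, adjusted p = 0.0444, or adjusted p = 0.83 with an estimated correlation), with Ifi47 at -0.57 ± 0.23 and Icam1 at -0.64 ± 0.31 (-0.38 without SAMHD1 KO 1). NF-kB targets fell as well (19 of 26 negative, adjusted p = 0.045, or adjusted p = 0.779 with an estimated correlation), although Bcl3 differed by 1.44 ± 0.50 while Cxcl2, a neutrophil chemokine, differed by -1.37 ± 0.49 (-0.88 without SAMHD1 MDA5 DKO 3). In both lists 0 members passed adjusted over the list alone. Without SAMHD1 KO 1 the adjusted p was 0.564 for each, without SAMHD1 MDA5 DKO 3 it was 0.268 for interferon gamma targets and 0.0784 for NF-kB targets, and without SAMHD1 MDA5 DKO 1 it was 0.0962 for the latter.

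Cell cycle genes rose as a list in SAMHD1 MDA5 DKO against SAMHD1 KO (37 of 40 positive, adjusted p = 7.74e-04, or adjusted p = 0.831 with an estimated correlation), with Mcm2 and Mcm4, subunits of the replicative helicase, at 1.25 ± 0.52 and 0.83 ± 0.32. DNA repair genes rose (25 of 30 positive, adjusted p = 1.69e-04, or adjusted p = 0.307 with an estimated correlation), with Parp1 at 0.53 ± 0.18 and Atr at 0.73 ± 0.26 (0.48 without SAMHD1 MDA5 DKO 3). Cholesterol biosynthesis rose (17 of 20 positive, adjusted p = 8.89e-05, or adjusted p = 0.779 with an estimated correlation), with Sqle, which encodes squalene epoxidase, at 3.36 ± 1.21. Members passing adjusted over the list alone numbered 0 in these 3 lists. Mast cell markers fell (10 of 10 negative, adjusted p = 7.74e-04, or adjusted p = 0.779 with an estimated correlation), with Cpa3 at -3.88 ± 1.64, Cma1 at -3.90 ± 1.69 (-2.13 and -2.01 without SAMHD1 MDA5 DKO 2) and 0 adjusted over the list alone. Erythroid markers fell (4 of 4 negative, adjusted p = 1.26e-05, or adjusted p = 0.307 with an estimated correlation), with 4 down adjusted over the list alone. Hba-a2 and Hbb-bt, both haemoglobin genes, differed by -5.65 ± 1.42 and -4.25 ± 1.09. The erythroid mean was 7.13, 6.90 and 6.40 in SAMHD1 KO and 0, 0.46 and 4.11 in SAMHD1 MDA5 DKO. Without SAMHD1 KO 1 the cell cycle list turned down (adjusted p = 0.379) and that of DNA repair had an adjusted p of 0.106, and without SAMHD1 MDA5 DKO 2 the cell cycle had 0.0618.

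Over all genes limma called 2, both down: Ifih1 at -8.81 ± 1.15 and Gca (ENSMUSG00000026893, chromosome 2, 62664285 to 62694109) at -1.48 ± 0.19, each with an adjusted p of 0.0358. Gca, a calcium-binding protein gene 18030 bases from Ifih1, gave 449, 336 and 449 normalised reads in SAMHD1 MDA5 DKO and 1253, 1082 and 1078 in SAMHD1 KO. At an unadjusted p under 0.05 there were 1333 genes, and 18.3% of genes had groups that did not overlap, against 10% by chance. The count was 133 without SAMHD1 KO 1 and 0 without SAMHD1 KO 2, SAMHD1 KO 3, SAMHD1 MDA5 DKO 1 or SAMHD1 MDA5 DKO 2, and 1 without SAMHD1 MDA5 DKO 3, where Gca was lost (adjusted p = 0.101). voom called 0, or 6597 with library quality weights, and limma with array quality weights called 6795. The authors' table has 98 up and 412 down, with 0 of the interferon list up and 5 down. The interferon mean stood at 10.56, 10.54 and 9.88 in SAMHD1 MDA5 DKO, -0.37 against SAMHD1 KO (exact permutation p = 0.1), and the difference was -0.14 without SAMHD1 MDA5 DKO 3. It was -0.17 outside the adjusted set and -0.77 inside.

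**Figure D3:**
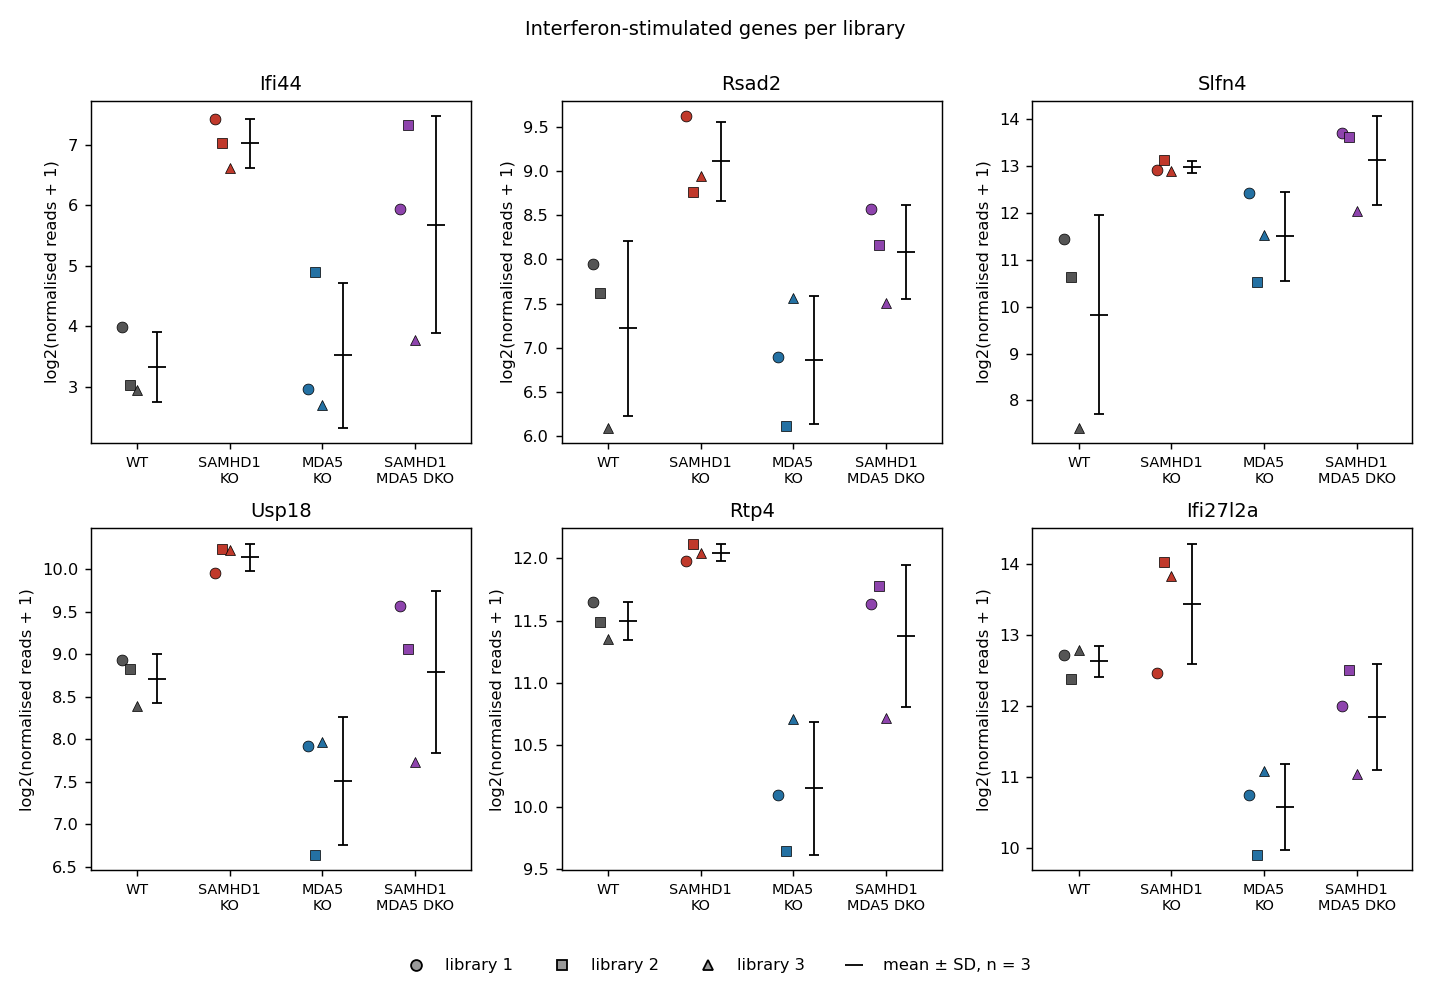
Log2 of normalised reads plus 1 for 6 interferon-stimulated genes in each of 12 libraries; black bars give the mean and SD of 3 libraries. Usp18 was 9.95 to 10.24 in SAMHD1 KO, 8.39 to 8.93 in WT, 7.73 to 9.57 in SAMHD1 MDA5 DKO and 6.64 to 7.96 in MDA5 KO.

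MDA5 KO was compared with WT to ask what the loss of MDA5 changes where SAMHD1 is present. Single interferon-stimulated genes were lower in MDA5 KO: 10 members of the list were down and 1 up adjusted over the list alone. Ifi27l2a differed by -2.06 ± 0.45, Rtp4 by -1.35 ± 0.30, Nmi by -1.24 ± 0.27 and Oas1a, one of the synthetases that activate RNase L, by -1.19 ± 0.25. The list as a whole did not pass (adjusted p = 0.0887), with 45 members positive and 49 negative. Over 17 other settings, left-out single libraries apart, its adjusted p ran from 6.28e-11 to 0.215 and it passed downwards in 7, among them the fit on the deposited values, where WT 3 holds no information of its own. MHC class I genes fell (14 of 20 negative, adjusted p = 0.0436, or adjusted p = 0.964 with an estimated correlation), with H2-T22 at -1.01 ± 0.30 and H2-T23 at -0.74 ± 0.21. Genes of dNTP metabolism fell (19 of 24 negative, adjusted p = 0.0306, or adjusted p = 0.964 with an estimated correlation), with Pnp at -0.68 ± 0.19 and Nme2 at -0.999 ± 0.37. NF-kB targets rose (21 of 26 positive, adjusted p = 0.0479, or adjusted p = 0.964 with an estimated correlation), with Nlrp3 at 0.83 ± 0.27 and Nfkbiz at 1.22 ± 0.44. DNA repair genes rose (23 of 30 positive, adjusted p = 0.0315, or adjusted p = 0.964 with an estimated correlation), with 4 up adjusted over the list alone, among them Brca2 at 1.54 ± 0.31 and Prkdc at 1.30 ± 0.31, while the lists of MHC class I, dNTP metabolism and NF-kB had 0. Without WT 1 the adjusted p was 0.19 for MHC class I and for NF-kB targets and 0.0854 for DNA repair. Without MDA5 KO 2 it was 0.143 for MHC class I and 0.0636 for DNA repair. It was 0.113 for MHC class I without MDA5 KO 1, 0.299 for NF-kB without MDA5 KO 3, 0.0787 for DNA repair without WT 2 and 0.301 for dNTP metabolism without WT 3, where the difference in list means turned from -0.33 to 0.026. In MDA5 KO 2, 800 of 1038 olfactory receptor genes had a read, against 107 to 194 in the other 11 libraries.

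Of all genes, limma called Ifih1 alone between MDA5 KO and WT, down at -9.12 ± 1.15 (adjusted p = 0.0499). At an unadjusted p under 0.05 there were 3383 genes, and groups did not overlap in 28.1% of genes. voom called 0, or 291 with library quality weights, and limma with array quality weights called 4392. Without any of WT 1, WT 2, MDA5 KO 1 or MDA5 KO 3 limma's count was 0, and without WT 3 it was 2, both up, with Ifih1 lost (adjusted p = 0.0657). limma without trend and the fit without a filter each called 1 other gene, with Ifih1 at an adjusted p of 0.0814 and 0.06. The authors' table has 347 up and 334 down, with 1 of the interferon list up and 16 down. The mean of the interferon list was 9.73, 9.47 and 9.88 in MDA5 KO, a difference of -0.09 from WT (exact permutation p = 0.9) that was -0.50 without WT 3. It turned to 0.15 without WT 1, 0.09 without WT 2 and 0.02 without MDA5 KO 2, and camera's adjusted p for the list, downwards, was 5.18e-12 without WT 3 and 0.0155 without MDA5 KO 3.

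SAMHD1 MDA5 DKO was compared with MDA5 KO to ask what the loss of SAMHD1 changes without MDA5. Interferon-stimulated genes were higher in SAMHD1 MDA5 DKO, with 88 of 94 members positive and a median difference of 0.49. Oasl1 differed by 2.38 ± 0.60, Rtp4 by 1.22 ± 0.30, Slfn1 by 1.09 ± 0.27 and Oas1g by 1.02 ± 0.29. The list rose in camera (adjusted p = 5.75e-45, or adjusted p = 0.0916 with an estimated correlation), with 0 members passing adjusted over the list alone. Interferon gamma and IRF1 targets rose (18 of 22 positive, adjusted p = 1.32e-14, or adjusted p = 0.103 with an estimated correlation), with Iigp1 at 1.96 ± 0.61 and Ifi47 at 0.74 ± 0.23. MHC class I genes rose (19 of 20 positive, adjusted p = 1.92e-06, or adjusted p = 0.105 with an estimated correlation), with H2-Q7 at 0.66 ± 0.37 and Nlrc5, their transactivator, at 0.85 ± 0.38. H2-Q7 was 0.31 without MDA5 KO 2, 0.99 without MDA5 KO 3, 0.39 without SAMHD1 MDA5 DKO 1 and 1.05 without SAMHD1 MDA5 DKO 3. Nucleic acid sensors rose (21 of 28 positive, adjusted p = 6.48e-05, or adjusted p = 0.0916 with an estimated correlation), with Zbp1 at 0.81 ± 0.26 and Tmem173, which encodes STING, at 0.55 ± 0.21. The sensor list shares members with the type I interferon list, Zbp1 among them.

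Targets of p53 fell in SAMHD1 MDA5 DKO against MDA5 KO, with 20 of 23 negative. The median difference was only -0.08 and the mean -0.32. The list passed camera both ways (adjusted p = 7.58e-05, or adjusted p = 0.0376 with an estimated correlation). It was the only one of the 24 in any comparison to do so. Its estimated correlation, -0.00685, lay below the preset 0.01, and fry's test of a shared direction did not pass (adjusted p = 0.0576). The adjustment covered the lists of this comparison only, so a single pass among all comparisons may be due to chance. Phlda3 differed by -1.68 ± 0.44 and Gdf15, a stress-induced cytokine, by -1.72 ± 0.68. Cell cycle genes fell (39 of 40 negative, adjusted p = 1.79e-10, or adjusted p = 0.302 with an estimated correlation), with Ube2c at -1.15 ± 0.47 and Mki67 at -0.84 ± 0.49 (-0.50 without SAMHD1 MDA5 DKO 1). Stress and immediate early genes fell (21 of 25 negative, adjusted p = 0.00716, or adjusted p = 0.203 with an estimated correlation), with Fos at -0.50 ± 0.30 (-0.061 without MDA5 KO 3) and Fosb at -1.05 ± 0.51 (-1.61 without SAMHD1 MDA5 DKO 3). Markers of other cell types fell with them. These were the lists of T cells (adjusted p = 0.00138, or adjusted p = 0.203 with an estimated correlation), NK cells (adjusted p = 4.03e-04, or adjusted p = 0.105 with an estimated correlation) and mast cells (adjusted p = 2.14e-05, or adjusted p = 0.203 with an estimated correlation). Neutrophil markers (adjusted p = 0.00934, or adjusted p = 0.203 with an estimated correlation) and eosinophil markers (adjusted p = 9.41e-04, or adjusted p = 0.105 with an estimated correlation) fell, as did endothelial markers (adjusted p = 0.00502, or adjusted p = 0.105 with an estimated correlation) and erythroid markers (adjusted p = 0.00536, or adjusted p = 0.259 with an estimated correlation). Among these, Klrk1 differed by -2.52 ± 0.87, S100a9 by -2.65 ± 1.71 (-4.81 without MDA5 KO 1, -1.01 without MDA5 KO 3), Siglecf by -1.37 ± 0.62 (-0.77 without SAMHD1 MDA5 DKO 2) and Egfl7 by -1.31 ± 0.54. Members passing adjusted over the list alone numbered 0 in all 14 lists of this comparison. The NK cell, eosinophil, endothelial and erythroid lists had 4 tested members each. NK cell reads were few, with means of 2.21, 2.28 and 1.03 (log2) in SAMHD1 MDA5 DKO. MDA5 KO 2 held the highest MDA5 KO mean for T cells (4.72), NK cells (4.31) and endothelial markers (5.40). MDA5 KO 3 held it for mast cell, neutrophil, eosinophil and erythroid markers. Whether cell composition differed was not tested. Without MDA5 KO 3 the adjusted p was 0.555 for stress genes, 0.421 for neutrophils and 0.18 for erythroid markers, and without MDA5 KO 2 it was 0.0663 for T cells and 0.0879 for neutrophils. It was 0.148 without SAMHD1 MDA5 DKO 1 and 0.0548 without SAMHD1 MDA5 DKO 2 for erythroid markers, and 0.106 without SAMHD1 MDA5 DKO 3 for endothelial markers.

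limma called 0 genes between SAMHD1 MDA5 DKO and MDA5 KO, Samhd1 at -2.39 ± 0.37 included (adjusted p = 0.419), with 154 genes at an unadjusted p under 0.05, or 1.02% of those tested. Groups did not overlap in 7.04% of genes, below the 10% of chance. voom called 0, or 1 with library quality weights, and limma called 2 with array quality weights and 1 with WT 3 left out of the shared spread. The authors' table has 37 up and 13 down, with 28 of the interferon list up and 0 down. The interferon mean differed by 0.64 (exact permutation p = 0.2), with 1 SAMHD1 MDA5 DKO library, at 9.88, below the highest MDA5 KO library.

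SAMHD1 MDA5 DKO was compared with WT to ask what remains of the SAMHD1 KO difference without MDA5. Interferon-stimulated genes were higher in SAMHD1 MDA5 DKO, with 70 of 94 members positive and a median difference of 0.48. Slfn4 differed by 3.28 ± 0.83 (2.08 without WT 3), Helz2 by 1.71 ± 0.28, Rnf213 by 1.63 ± 0.43 and Parp10 by 0.98 ± 0.24. The list rose in camera (adjusted p = 0.00295, or adjusted p = 0.798 with an estimated correlation), with Helz2 the only member up adjusted over the list alone, and the list's adjusted p was 0.241 without WT 3, or 0.208 in voom without WT 3. Genes of dNTP metabolism fell (23 of 24 negative, adjusted p = 0.00295, or adjusted p = 0.749 with an estimated correlation), with Nt5c at -0.87 ± 0.29 and Cmpk1 at -0.91 ± 0.32, or -0.57 and -0.45 without WT 3. Mast cell markers fell (10 of 10 negative, adjusted p = 0.00238, or adjusted p = 0.749 with an estimated correlation), with Cpa3 at -4.82 ± 1.64 (-3.09 without WT 2, -3.08 without SAMHD1 MDA5 DKO 2) and Mrgprb1 at -4.23 ± 1.27. The dNTP and mast cell lists had 0 members passing adjusted over the list alone. The mast cell mean was 9.47 in WT 2 against 4.16 and 6.53 in the other WT libraries, and its adjusted p was 0.0612 without WT 2. For dNTP metabolism it was 0.0944 without WT 3.

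The single gene that limma called between SAMHD1 MDA5 DKO and WT was Tpcn2 (ENSMUSG00000048677, chromosome 7, 145186524 to 145284011), an endolysosomal channel gene, up by 1.57 ± 0.20 (adjusted p = 0.047). Ifih1 and Samhd1, at -7.97 ± 1.15 and -2.01 ± 0.37, had adjusted p of 0.0563 and 0.127. At an unadjusted p under 0.05 there were 4203 genes, and groups did not overlap in 34.6% of genes. The count was 1784 without WT 1, 7 without WT 3, and 0 without WT 2, SAMHD1 MDA5 DKO 1 or SAMHD1 MDA5 DKO 2. voom called 1, or 1567 with library quality weights, and limma with array quality weights called 5765. On the deposited values limma called 1223, but the subtraction had removed spread between libraries that this fit does not account for. With the adjusted set as a term on the recovered reads it called 9. Without SAMHD1 MDA5 DKO 3 limma called 1 other gene, with Tpcn2 at an adjusted p of 0.115, as it also did without trend (Tpcn2 0.0637) and without a filter (Tpcn2 0.108). The authors' table has 1008 up and 1093 down, with 17 of the interferon list up and 1 down. The interferon mean differed by 0.55 (exact permutation p = 0.3), and by 0.13 without WT 3. It was 0.36 outside the adjusted set and 0.92 inside.

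SAMHD1 KO and MDA5 KO, compared because the authors deposited this pair, differed by 1.002 in the mean of the interferon list. Of 94 members, 87 were higher in SAMHD1 KO, and 34 were up and 0 down adjusted over the list alone. Ifi27l2a differed by 2.86 ± 0.45, Usp18 by 2.64 ± 0.44, Rtp4 by 1.89 ± 0.30 and Phf11d by 1.09 ± 0.19. The list rose in camera (adjusted p = 3e-27, or adjusted p = 0.283 with an estimated correlation), and fry gave an adjusted p of 0.0997 for its test of a shared direction. Its mixed test, of members that differ in any mix of directions, gave an adjusted p of 0.00861. Interferon gamma and IRF1 targets rose (18 of 22 positive, adjusted p = 2.89e-09, or adjusted p = 0.283 with an estimated correlation), with 9 up adjusted over the list alone, Iigp1 at 2.91 ± 0.61 and Ifi47 at 1.30 ± 0.23. MHC class I genes rose (17 of 20 positive, adjusted p = 2.84e-05, or adjusted p = 0.283 with an estimated correlation), with H2-Q7 at 1.39 ± 0.37 and H2-T23 at 0.63 ± 0.21.

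Cell cycle genes fell in SAMHD1 KO against MDA5 KO (39 of 40 negative, adjusted p = 7.78e-12, or adjusted p = 0.512 with an estimated correlation), with Mcm2 at -1.68 ± 0.52 and Mcm4 at -1.09 ± 0.32. DNA repair genes fell (25 of 30 negative, adjusted p = 2.59e-06, or adjusted p = 0.243 with an estimated correlation), with Brca2 at -1.26 ± 0.31 and Exo1 at -1.80 ± 0.44, the 2 down adjusted over the list alone. Cholesterol biosynthesis fell (18 of 20 negative, adjusted p = 1.6e-04, or adjusted p = 0.588 with an estimated correlation), with Sqle at -3.50 ± 1.21. Small peritoneal macrophage and monocyte markers fell as a list (14 of 19 negative, adjusted p = 0.0285, or adjusted p = 0.512 with an estimated correlation) with members apart, F13a1 at -2.16 ± 0.38 and Plac8 at 3.69 ± 0.98. Erythroid markers rose (4 of 4 positive, adjusted p = 9.24e-04, or adjusted p = 0.395 with an estimated correlation), with Hba-a2, the only member up adjusted over the list alone, at 4.66 ± 1.42 and Hba-a1 at 4.26 ± 1.68. For monocyte markers 1 was up and 3 were down adjusted over the list alone, and for the cell cycle, cholesterol and MHC class I lists 0 passed. The difference in cell cycle means, -1.22, was -0.36 without SAMHD1 KO 1 (adjusted p = 0.0485). Without SAMHD1 KO 1 the adjusted p was 0.0574 for erythroid and 0.541 for monocyte markers, and for the latter it was 0.109 without MDA5 KO 3.

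Among all genes limma called Ifih1 alone between SAMHD1 KO and MDA5 KO, higher in SAMHD1 KO by 9.95 ± 1.15 (adjusted p = 0.0196). There were 1442 genes at an unadjusted p under 0.05, and groups did not overlap in 15.9% of genes. The count was 174 without SAMHD1 KO 1 and 0 without SAMHD1 KO 2, SAMHD1 KO 3, MDA5 KO 1 or MDA5 KO 3. voom called 0, or 6035 with library quality weights, and limma with array quality weights called 6724. limma called 49 in a pairwise fit and 47 with WT 3 left out of the shared spread. The authors' table has 150 up and 100 down, with 36 of the interferon list up and 0 down. The interferon mean differed by 1.002 with all 3 SAMHD1 KO libraries above all 3 of MDA5 KO (exact permutation p = 0.1).

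**Figure D4:**
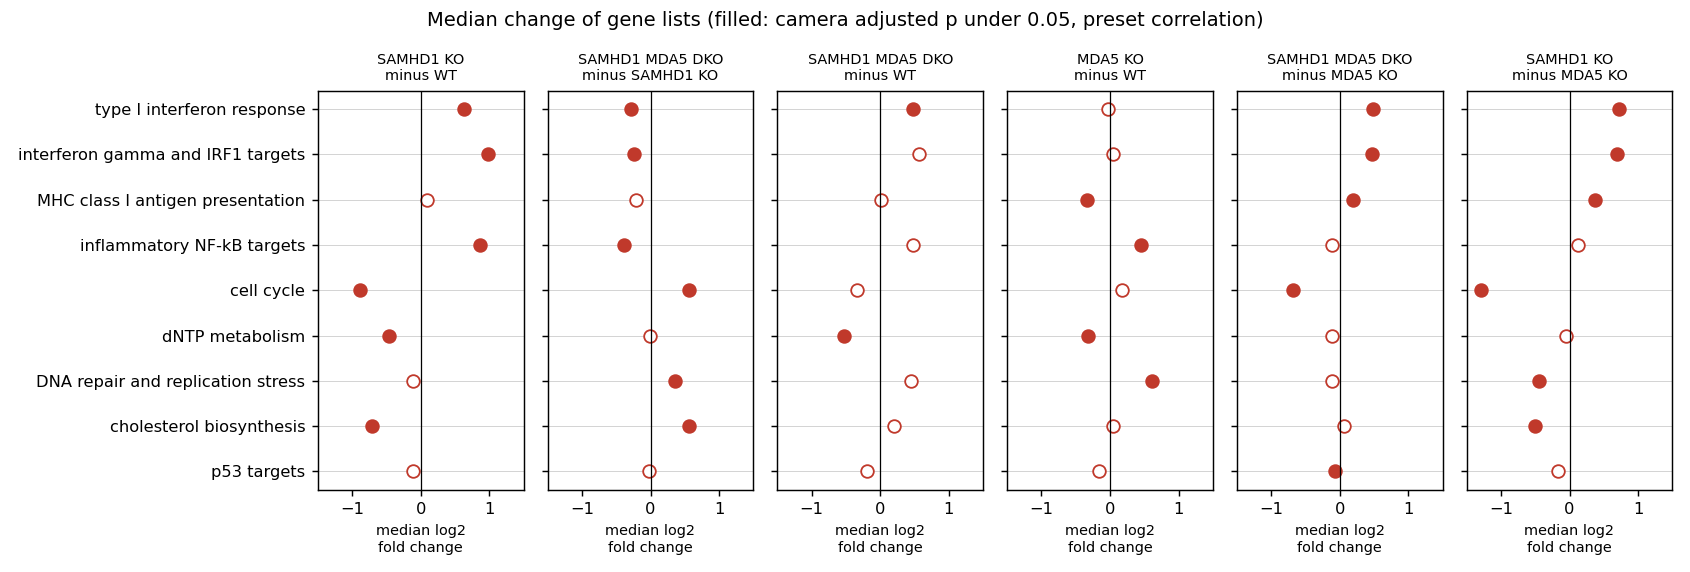
Median log2 fold change of 9 gene lists in the 6 pairwise comparisons; filled points passed camera at an adjusted p under 0.05 with the preset correlation. The median of the type I interferon list was 0.63 in SAMHD1 KO minus WT, -0.28 in SAMHD1 MDA5 DKO minus SAMHD1 KO and 0.49 in SAMHD1 MDA5 DKO minus MDA5 KO.

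The interaction asked whether the loss of MDA5 acts differently with and without SAMHD1. For interferon-stimulated genes no such difference was detected: 34 members were positive and 60 negative, with a median of -0.21 and a camera adjusted p of 0.643. Slfn1 and Oas1a gave 0.82 ± 0.39 and 0.73 ± 0.35, and Helz2 gave -0.79 ± 0.40 (-0.49 without SAMHD1 KO 1). limma called 0 genes in the interaction, with 485 at an unadjusted p under 0.05. voom called 0, or 198 with library quality weights, and limma with array quality weights called 1333. The mean of the list was -0.28, and 0.13 without WT 3, and camera's adjusted p for the list was 0.00223 upwards without WT 3. It was 0.0431 downwards without WT 1.

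Of the interferon list, 76 of 94 members were positive both in SAMHD1 KO minus WT and in SAMHD1 MDA5 DKO minus MDA5 KO, which share no library, and 1 was negative in both, against 75.8 and 0.83 if the signs were independent. In MDA5 KO minus WT and SAMHD1 MDA5 DKO minus SAMHD1 KO, 44 members were negative in both and 19 positive in both, against 36.5 and 11.5. Among all genes, 1 was called down in both of the latter comparisons, Ifih1. Over the 24 lists, fry's test of a shared direction passed 0 in each of the 7 comparisons. Its mixed test passed 2 in SAMHD1 KO minus WT, 3 in SAMHD1 MDA5 DKO minus WT, 3 in MDA5 KO minus WT, 5 in SAMHD1 KO minus MDA5 KO and 0 in the others.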

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

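The tests of a wrong label for WT 3, of a library deposited again and of a shared preparation of SAMHD1 KO 2 and 3, and of the distance between Gca and Ifih1 were chosen after the values were seen, that of the label in place of 3 bounds on Samhd1, of which a rank among 7 libraries could not have been passed. By camera's test of the interaction, 4 gene lists responded differently to the loss of MDA5 with and without SAMHD1. Inflammatory NF-kB targets had a median difference of -0.38 in the SAMHD1 KO background and 0.45 in the WT background (interaction adjusted p = 3.32e-05, or adjusted p = 0.475 with an estimated correlation), with Tnfaip3 at -1.67 ± 0.58 and Birc3 at -1.18 ± 0.41. Cholesterol biosynthesis had medians of 0.56 and 0.05 (interaction adjusted p = 6.48e-05, or adjusted p = 0.93 with an estimated correlation), with Msmo1 at 0.78 ± 0.32. Erythroid markers had medians of -5.46 and -1.06 (interaction adjusted p = 0.00286, or adjusted p = 0.93 with an estimated correlation). Genes of dNTP metabolism had medians of -0.01 and -0.32 (interaction adjusted p = 0.0342, or adjusted p = 0.93 with an estimated correlation, or adjusted p = 0.0516 in the version of camera run first), with Nme1 at 0.77 ± 0.45 (0.33 without WT 3). Without WT 1 the adjusted p was 0.074 for cholesterol and 0.105 for erythroid markers. For dNTP metabolism it was 0.926 without WT 3, where the interaction of list means went from 0.37 to 0.0089, 0.494 without SAMHD1 KO 1, 0.055 without MDA5 KO 1, 0.0801 without MDA5 KO 2, 0.0714 without SAMHD1 MDA5 DKO 2 and 0.067 without SAMHD1 MDA5 DKO 3. No explanation was tested for these.

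WT 3 stood apart from the other 11 libraries, at -182.3 on a first principal component that held 39.7% of the variance, and its interferon list lay lower, by a median of -0.90 against the mean of WT 1 and WT 2. Lower depth is argued against only as the full cause of fewer genes detected in WT 3. WT 1 and WT 2 thinned to the total of WT 3 still detected 18336 and 20349 genes against 17783, or 3.11% and 14.4% more. The interferon list and the component were not measured after thinning, so that this test cannot decide about them. A swapped label with a genotype without SAMHD1 is argued against only as the cause of the low interferon mean. At 8.96 it lay at -4.85 SD from the mean of the 6 libraries without SAMHD1 and below the lowest of them, 9.88. Whether the label is right was not decided by this, since the low mean is part of the pattern and was known when the bound was set. Samhd1 lay between the groups, 0.51 log2 above the highest of the 6 and 1.14 log2 below the lower other WT library. Ifih1 lay 4.25 log2 above the highest library without MDA5, which argues against a swap with a genotype without MDA5. A bias by GC content or gene length stays open as a part of the gap, which was -0.63 (95% bootstrap interval -0.86 to -0.38) after its trend was removed. Lyz2 and Gm42418, chosen after their values were seen, set WT 3 apart too. Lyz2 was at 17.72 (log2) against at least 20.47 elsewhere, and Gm42418 held 3.06% of the reads against at most 0.918% elsewhere. Whether this bears on the interferon gap was not tested. No biological explanation and no other kind of wrong label was tested.

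SAMHD1 KO 2 and 3 were closer than any other pair within a genotype, with a mean chi-square per gene of 6.97 against 54.8 to 836 in the other 11 pairs. A copy of the same reads would show no difference, and the mean argues against that. A library sequenced again would give about 1 if counting error alone acted, and the mean argues against it only on that condition. The median was 1.69 against 6.73 to 67.03 in the other 11 pairs, so that high values in part of the genes raised the mean. A shared preparation may account for the closeness and cannot be told apart, because 1 of the 2 libraries lies in the authors' adjusted set and no label says what that set is. Both were counted as separate libraries. No biological explanation was tested.

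Gca lay lower in the 6 libraries without MDA5, by -1.24 ± 0.14 in the joint contrast of both MDA5-deficient genotypes against the others. Reads shared through overlap with Ifih1 are argued against by 18030 bases between the annotated spans. A regional difference carried along with the targeted locus, such as flanking sequence of another strain, may account for it and cannot be told apart: of 84 neighbours within 10 Mb, 26.2% passed an unadjusted p of 0.05 against 26.1% of the other genes (one-sided Fisher's exact p = 0.53). That share cannot show a difference confined to the nearest genes. Fap, which starts at 62500943 on the other side of Ifih1, lay lower too, by -3.29 ± 0.85 (limma's adjusted p = 0.0927). Farther off, Gpd2 and Wdsub1 lay higher, by 0.78 ± 0.20 and 0.61 ± 0.16 (adjusted p = 0.0927 each). These 3 genes were chosen after their values were seen. An effect of MDA5 on Gca, the biological explanation that the design gives, stays open and untested.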

How the results depend on the processing

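The counts of genes called moved with many settings. The interferon list response kept its sign in the comparisons other than MDA5 KO minus WT and the interaction, under the alternatives run. The cause was not tested for any change below, except where fewer libraries were used. A limit is the spread shared by all comparisons: with WT 3 left out of it, 47 genes were called in SAMHD1 KO minus MDA5 KO against 1 with it. In SAMHD1 MDA5 DKO minus MDA5 KO 1.02% of genes had an unadjusted p under 0.05.

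With a library left out, genes called ranged from 0 to 2 in SAMHD1 KO minus WT, 0 to 133 in SAMHD1 MDA5 DKO minus SAMHD1 KO, 0 to 1784 in SAMHD1 MDA5 DKO minus WT, 0 to 2 in MDA5 KO minus WT and 0 to 174 in SAMHD1 KO minus MDA5 KO. Lists passing ranged from 3 to 11 in SAMHD1 MDA5 DKO minus SAMHD1 KO (3 without SAMHD1 KO 1), 2 to 8 in SAMHD1 MDA5 DKO minus WT (8 without WT 1), 2 to 7 in MDA5 KO minus WT (7 without WT 3, 2 without WT 1 or MDA5 KO 2) and 3 to 7 in the interaction (7 without MDA5 KO 3). The interferon response ranged from -0.50 to 0.15 in MDA5 KO minus WT and -0.52 to 0.13 in the interaction. Camera's adjusted p for the interferon list ranged from 5.18e-12 to 0.992 in MDA5 KO minus WT and 0.00223 to 0.887 in the interaction, and it lost its call in SAMHD1 MDA5 DKO minus SAMHD1 KO without SAMHD1 KO 1 (0.27) or SAMHD1 MDA5 DKO 3 (0.148) and in SAMHD1 MDA5 DKO minus WT without WT 3 (0.241). Over the other settings it passed downwards in 16 of 18 in SAMHD1 MDA5 DKO minus SAMHD1 KO (1.02e-06 to 0.506), lost with voom's library quality weights (0.506) and array quality weights (0.442). It passed in 15 of 17 in SAMHD1 MDA5 DKO minus WT (5.54e-06 to 0.234), lost in voom with WT 3 left out (0.208) and without WT 3 and MDA5 KO 2 (0.234). In MDA5 KO minus WT it came to pass downwards in 7 of 17 (6.28e-11 to 0.215): without a filter (0.00143), with the adjusted set as a term (7.85e-05), voom's library quality weights (1.78e-06) or array quality weights (5.48e-04), in voom with WT 3 left out (8.98e-11), without WT 3 and MDA5 KO 2 (6.42e-09) and on the deposited values (6.28e-11). Ifih1 ranged from -0.12 to 2.46 in SAMHD1 MDA5 DKO minus MDA5 KO and -0.95 to 1.62 in the interaction. Samhd1 ranged from -0.016 to 0.62 in MDA5 KO minus WT and -0.45 to 0.31 in SAMHD1 MDA5 DKO minus SAMHD1 KO.

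Under the planned settings, limma without trend called 1 gene in SAMHD1 KO minus WT, 0 in SAMHD1 MDA5 DKO minus SAMHD1 KO and 0 in SAMHD1 KO minus MDA5 KO, with 2 lists in MDA5 KO minus WT. It called 1 gene in SAMHD1 MDA5 DKO minus WT and 1 in MDA5 KO minus WT, as did the fit without a filter, sharing 0 with the genes called otherwise (Tpcn2 and Ifih1). Without a filter the counts were 0 in SAMHD1 MDA5 DKO minus SAMHD1 KO and 5 in SAMHD1 KO minus MDA5 KO, with 11 lists in SAMHD1 MDA5 DKO minus WT and 9 in SAMHD1 MDA5 DKO minus MDA5 KO, and the interaction's interferon list turned up (adjusted p = 0.84). With a mean of at least 50 reads, MDA5 KO minus WT called 0 genes and 2 lists, SAMHD1 MDA5 DKO minus MDA5 KO 9 lists and the interaction 2 lists. Pairwise fits called 0 in SAMHD1 MDA5 DKO minus SAMHD1 KO, 0 in SAMHD1 MDA5 DKO minus WT, 0 in MDA5 KO minus WT and 49 in SAMHD1 KO minus MDA5 KO. The numbers of the libraries were not taken to pair them, since 8 of 18 pairs of the same number correlated above 0.1 (from -0.06 to 0.34) where all were required to. As 9 of 12 libraries correlated best with one of their own number, a pairing is not excluded. The replicate block called 0 in SAMHD1 MDA5 DKO minus SAMHD1 KO, 0 in SAMHD1 MDA5 DKO minus WT, 0 in MDA5 KO minus WT with 2 lists, and 2 in SAMHD1 KO minus MDA5 KO. With it the lists of interferon gamma targets and of NF-kB targets had an adjusted p of 0.0508 in SAMHD1 MDA5 DKO minus SAMHD1 KO, and those of MHC class I and NF-kB 0.0509 in MDA5 KO minus WT. Lists that came to pass were erythroid markers in SAMHD1 KO minus WT (0.0427), NK cells in SAMHD1 MDA5 DKO minus WT (0.0483), DNA repair in SAMHD1 MDA5 DKO minus MDA5 KO (0.0215) and the cell cycle in the interaction (0.0207). A pseudocount of 0.1 called 0 in SAMHD1 MDA5 DKO minus SAMHD1 KO, MDA5 KO minus WT and SAMHD1 KO minus MDA5 KO. A pseudocount of 10 called 2 in SAMHD1 MDA5 DKO minus WT and turned Ifih1 to -0.40 in the interaction. The estimated correlation passed 0 lists in every comparison except SAMHD1 MDA5 DKO minus MDA5 KO, with 1. The median over the list gave an interferon response of 0.73 in SAMHD1 KO minus MDA5 KO. edgeR, the main test planned for counts, and the DESeq2 alternative were not run, for lack of a deposited count column. How the genes called would differ under them is not known.

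The following settings were chosen after seeing the data. Trimmed mean of M-values scaling and total-read scaling each called 0 in SAMHD1 MDA5 DKO minus SAMHD1 KO and 0 in MDA5 KO minus WT, and total-read scaling, which moved the median of all genes by 0.11 there, turned Samhd1 to 0.0132 in SAMHD1 MDA5 DKO minus SAMHD1 KO. With the adjusted set as a term, 9 genes were called in SAMHD1 MDA5 DKO minus WT, 0 in MDA5 KO minus WT and 11 in SAMHD1 KO minus MDA5 KO, and the interaction's interferon list turned up (adjusted p = 0.423). voom called 0 in SAMHD1 MDA5 DKO minus SAMHD1 KO, 0 in MDA5 KO minus WT and 0 in SAMHD1 KO minus MDA5 KO, with Samhd1 at 0.0142 in SAMHD1 MDA5 DKO minus SAMHD1 KO. The median of all genes moved by 0.115 there, by 0.115 in voom with WT 3 left out and by 0.13 in voom with library quality weights. In the latter 2 settings it moved by -0.104 and -0.112 in MDA5 KO minus WT and by 0.184 and 0.203 in the interaction. voom with WT 3 left out called 9 in SAMHD1 MDA5 DKO minus SAMHD1 KO (Samhd1 0.0122), 6 in SAMHD1 MDA5 DKO minus WT with 1 list, 30 in SAMHD1 KO minus MDA5 KO, with Samhd1 at -0.054 in MDA5 KO minus WT and 0.066 in the interaction, whose interferon list turned up (adjusted p = 0.00591). voom with library quality weights called 2771 in SAMHD1 KO minus WT, 6597 in SAMHD1 MDA5 DKO minus SAMHD1 KO with 2 lists and Samhd1 at 0.28, 1567 in SAMHD1 MDA5 DKO minus WT, 291 in MDA5 KO minus WT with Samhd1 at -0.029, 1 in SAMHD1 MDA5 DKO minus MDA5 KO, 6035 in SAMHD1 KO minus MDA5 KO and 198 in the interaction, with Samhd1 at 0.31 and the interferon list up (adjusted p = 0.00779). Array quality weights called 6829 in SAMHD1 KO minus WT, 6795 in SAMHD1 MDA5 DKO minus SAMHD1 KO with 3 lists and Samhd1 at 0.16, 5765 in SAMHD1 MDA5 DKO minus WT with 11 lists, 4392 in MDA5 KO minus WT with 11 lists, 2 in SAMHD1 MDA5 DKO minus MDA5 KO, 6724 in SAMHD1 KO minus MDA5 KO and 1333 in the interaction, with Samhd1 at 0.11 and the interferon list up (adjusted p = 0.122). These array weights ran from 0.0558 for WT 3 to 9.10 for SAMHD1 KO 3 and 6.61 for WT 2, so that such counts rest on few libraries. With SAMHD1 KO 2 and 3 averaged, 0 genes were called in SAMHD1 MDA5 DKO minus SAMHD1 KO, SAMHD1 MDA5 DKO minus WT, MDA5 KO minus WT and SAMHD1 KO minus MDA5 KO. Without WT 3 and MDA5 KO 2, counts were 1 in SAMHD1 KO minus WT, 4 in SAMHD1 MDA5 DKO minus SAMHD1 KO, 6 in SAMHD1 MDA5 DKO minus WT, 2 in MDA5 KO minus WT with 7 lists and 3 in SAMHD1 KO minus MDA5 KO, and the interaction's interferon list turned up (adjusted p = 0.298). With WT 3 left out of the shared spread, counts were 6 in SAMHD1 MDA5 DKO minus SAMHD1 KO, 1 in SAMHD1 MDA5 DKO minus MDA5 KO and 47 in SAMHD1 KO minus MDA5 KO. On the deposited values of each table alone, counts were 2 in SAMHD1 KO minus WT, 8 in SAMHD1 MDA5 DKO minus SAMHD1 KO, 1223 in SAMHD1 MDA5 DKO minus WT with 5 lists, 0 in MDA5 KO minus WT with 8 lists and 0 in SAMHD1 KO minus MDA5 KO. In the 3 tables with MDA5 KO, that fit counts a library without information of its own as a replicate, and the number of libraries behind its p is overstated. In the tables without MDA5 KO, the subtraction removed spread between libraries that the fit does not account for, so that its counts are too high there as well. On these values Samhd1 turned to -0.014 in MDA5 KO minus WT and Ifih1 to -0.021 in SAMHD1 MDA5 DKO minus MDA5 KO. The version of camera run first passed 2 lists in MDA5 KO minus WT. Of the other comparisons of a named gene with its alternatives, 2789 kept their direction and side of the threshold, 206 came to pass it and 62 no longer did. The main fit called 0 to 2 genes per comparison, so that most named genes had no call to lose. The 2789 therefore say little about how stable the calls were, and the 62 lost calls fall on the few called genes.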

Other observations

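Beyond the comparisons, large peritoneal macrophage markers moved both ways. Adjusted over the list alone, 5 were up and 3 down in MDA5 KO minus WT (fry's mixed test, adjusted p = 0.00796), 3 up and 3 down in SAMHD1 MDA5 DKO minus WT (adjusted p = 0.013) and 2 up and 0 down in SAMHD1 KO minus WT (adjusted p = 0.0578). Gata6, the transcription factor of these cells, lay between 12.26 and 12.90 and Timd4 between 14.50 and 15.79 (log2) in the 12 libraries. Their list had camera adjusted p from 0.271 to 0.894 over the 7 contrasts. The lists for MHC class II (0.194 to 0.998), B cells (0.151 to 0.862), dendritic cells (0.164 to 0.958) and mesothelial cells (0.195 to 0.958) passed in 0 contrasts, as did genes within 10 Mb of Samhd1 (0.212 to 0.897) and of Ifih1 (0.212 to 0.99). The lists of interferon genes and of sex-linked genes had 0 tested members, and that of fibroblasts and adipocytes had 2, too few for a test. These markers were given per library after their values were seen.

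Libraries differed in other cell types' markers. The B cell mean was 8.98 in WT 2 against 1.90 to 5.29 in the other 11 libraries. The erythroid mean was 6.95 in WT 3, 4.44 in WT 2 and 0.93 in WT 1. In WT 3, Lyz2, an abundant macrophage lysozyme gene, was at 17.72 against at least 20.47 elsewhere, Mx1 was at 3.39 against at least 7.20, and Gm42418, a predicted gene, held 3.06% of the reads against 0.156% to 0.918% in the others. These genes were chosen after their values were seen.

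In the authors' table of SAMHD1 KO minus WT, genes chosen after their values were seen include Angptl4 at 2.68 ± 0.36 (adjusted p = 7.88e-10), Ifi213 at 2.64 ± 0.33 (adjusted p = 1.19e-11), Scd2 at -2.61 ± 0.30 (adjusted p = 5.47e-14) and Lgals1 at -1.98 ± 0.36 (adjusted p = 3.96e-05). The subtraction described above was found in the library columns, and no label says whether these fold changes include it.

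The 6 libraries of a comparison split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. SAMHD1 KO minus WT called 0 genes, so that 10 of 10 splits had to call as many, and the highest of the 9 other splits called 267. In SAMHD1 MDA5 DKO minus SAMHD1 KO the real split called 2 and the highest other 0 (1 of 10 as large). SAMHD1 MDA5 DKO minus WT called 1 against 0 (1 of 10), as did MDA5 KO minus WT (1 of 10) and SAMHD1 KO minus MDA5 KO (1 of 10). SAMHD1 MDA5 DKO minus MDA5 KO called 0 against 2, and the 10 of 10 there were fixed in the same way. For the interaction the real count was 0 too, so that 100 of 100 regroupings, the real one included, had to give as many and the test says nothing about chance, and the highest gave 837. The split with 267 genes, which set WT 3, SAMHD1 KO 2 and SAMHD1 KO 3 against the others, points to a structure of those 6 libraries, and what it follows was not tested. The regrouping with 837 mixed the genotypes, and genotype differences can enter its count.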
